A study of Caenorhabditis elegans with 2 samples.

How the data were processed

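Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Caenorhabditis elegans hermaphrodites at the L4 larval stage, 48 hours after synchronization as starved L1 larvae. Per the labels, the worms carried an integrated transgene that made F10B5.3 with a C-terminal tag of green fluorescent protein and FLAG in an unc-119 mutant background, and the tagged protein was pulled down with an antibody against GFP. The series held 2 biological replicates of 1 group and no second group, so nothing was compared between conditions.

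Per the file headers and the notes deposited with the files, the authors called peaks in each replicate separately from its alignment and a control alignment. They also called peaks on the pooled alignments of both replicates. Irreproducible discovery rate (IDR) analysis of the 3 lists then gave the thresholded peak set, and each list was deposited for the ce11 and the ce10 build. The aligner, the peak caller, their versions and the IDR threshold were not given in the sources used here. The deposited signal value of each call came from the authors' peak caller, and its scale was not stated. It was used to describe, rank or filter calls within a list. Between lists it was used only to correlate and plot the signals of the replicates. The deposited −log10 q-value sat at the same ceiling, 3.24, for all 862 peaks of the thresholded set, so it did not order them. All deposited peak coordinates of the ce11 lists lay inside the chromosome lengths of the reference used here, WBcel235, which is the same assembly as ce11. The ce10 coordinates were used only within ce10 lists and never converted.

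Read counts and sequencing depth per replicate were not used here, so the depth is unknown. The relaxed lists, which hold weak calls as well as strong ones, contained 22211 calls in replicate 1, 27642 in replicate 2 and 30000 in the pool. For replicate 2 the builds differed in more than coordinates. Its ce11 list had a median width of 440 bp and 24 mitochondrial calls, and its ce10 list 27551 calls, 450 bp and 23. The reason is unknown. The other lists had the same median width in both builds. The 862 thresholded peaks were exactly the 862 pooled calls with the highest signal. They are called IDR peaks below. The 28818 pooled relaxed calls that overlapped no IDR peak served as the background, because they came from the same reads, mapping and caller. Confidence intervals of shares are 95% Wilson intervals over peaks. Those of odds ratios are 95% normal intervals on the log scale. Odds ratios over strata of summit GC are Mantel-Haenszel estimates, with strata cut at the deciles of the GC content within 50 bp of the nuclear IDR summits and the variance of Robins, Breslow and Greenland. All intervals cover counting error only. All p-values below were computed over peaks, genes or sequence windows and not over replicates, and they therefore do not measure the spread between worm cultures.

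Agreement of the replicates was measured between the 862 calls of highest signal in each relaxed list. A call was shared if its summit lay within 100 bp of a summit in the other set, and chance came from 1000 random shifts along the chromosomes, in a one-sided permutation test. The signal correlation used IDR peaks with a summit within 100 bp in both relaxed lists, on log10 values, with 100000 permutations, two-sided. Shares of peaks by chromosome, near a transcription start site (TSS) and near non-coding RNA genes were compared with the background by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the 6 nuclear chromosomes or the 9 gene classes. Annotation was Ensembl release 115. A summit was near a TSS if it lay within 1000 bp of the TSS of a protein-coding transcript, and at a non-coding RNA gene if it lay within 200 bp of that gene.

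A protein-coding gene was called bound if an IDR summit lay within 1000 bp of one of its TSSs. For 32 gene lists the share of bound members was compared with all other genes that had any pooled relaxed summit within 1000 bp, 9495 genes in all, by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the lists. For 30 fixed consensus motifs and all 2080 canonical 6-mers, presence on either strand within 50 bp of the summit was compared with presence in flanks 200 to 250 bp away on either side of the same peaks. This was an exact two-sided McNemar test, adjusted over the motifs or over the 6-mers. The loci of F10B5.3 and unc-119 were described by the highest relaxed signal and the number of relaxed calls within 20 kb of the gene midpoint. Each was given as a percentile among windows around 19973 protein-coding genes. Adjusted p-values below 0.05 were taken as past the threshold.

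Genes, peaks and words were named by a rule. It took the 20 highest IDR peaks, the 4 bound members with the highest peaks of each list past the threshold, up to 2 bound members of lists named as not past it, F10B5.3 and unc-119, all fixed motifs past the threshold and the 5 6-mers with the lowest adjusted p. Because 17 of the 20 highest peaks were mitochondrial, the 20 highest nuclear peaks were named as well. The main tests, gene lists, motifs and naming rule were fixed before the data were examined. The tests of the share near a TSS on X, on the autosomes and between them were not part of that plan. Settings chosen after seeing the data were the restriction to nuclear or autosomal calls, the naming of the highest nuclear peaks and the search for each of them in each replicate alone, the removal of calls near tRNA or other small RNA genes, and a background of shuffled summit sequences that keeps dinucleotide counts.

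Alternatives were the ce10 lists, a stricter peak set of the 431 highest peaks, merged peaks, other overlap rules, other distances and windows, other backgrounds, and each replicate alone. For each replicate alone, its 862 highest calls took the place of the IDR peaks and its own relaxed list gave the background. The list, word and chromosome tests were tested on simulated data. A list of the size of the cytosolic ribosomal proteins with members drawn at 5 times the weight of other genes was recovered in 100 of 100 draws over 9495 genes, and 0.02 other lists were called per draw. A word planted in 15% of 862 windows was recovered in 20 of 20 draws, with 4.95 other 6-mers called per draw. With no planted word 0.1 6-mers were called per draw. These windows lay at random nuclear positions and not at GC-rich summits. The rate of false calls therefore does not carry over to the comparison of summits with flanks. An X weight of 1.6 among 839 calls was recovered in 100 of 100 draws, with 0.52 other chromosomes called per draw, and 1 of 100 draws with equal weights called X. Scripts ran under Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.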

Results

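The genomic sites at which tagged F10B5.3, annotated as a BTB domain-containing protein and also named btbz-2, was recovered were mapped in L4 larvae in 2 biological replicates. The deposited set held 862 IDR peaks in the ce11 build, with a median width of 450 bp. Some wide regions held several summits, and merging overlapping peaks left 800 regions. Of the 862 peaks, 839 lay on the 6 nuclear chromosomes and 23 on the mitochondrial chromosome. Signal values are those of the authors' pooled list unless a replicate is named, and coordinates are in ce11.

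The strongest nuclear peaks lay mostly on the X chromosome, away from promoters. All of the 10 highest nuclear peaks were on X, as were 16 of the 20 highest and 21 of the 50 highest. The highest lay between protein-coding genes at X:11093875-11094470, with the summit at 11094217 and a signal of 1110. It was 3969 bp from the nearest TSS, that of W02H3.3. In the replicate lists its signal was 467 in replicate 1 and 644 in replicate 2. The next was at X:14525560-14526215, 734 bp from the TSS of nspc-17, with a signal of 961. The third, at X:4209006-4209550, had a signal of 926 and lay 1815 bp from the TSS of F20B6.9. Further X peaks between protein-coding genes had summits at 806708 (signal 903, 3930 bp from gtr-1) and 13700874 (879, 6033 bp from K02D3.1). Summits at 16682107 (807, 2567 bp from F22H10.2) and 9465841 (806, 2496 bp from ZK899.6) were also of this kind. Others were at 16056570 (765, 1025 bp from T27A8.7), 11937545 (680, 1381 bp from F55G7.5), 1627129 (639, 1008 bp from fbxb-58) and 12363192 (598, 1712 bp from F19H6.5). The peak with its summit at X:8036470 had a signal of 667 and lay 4843 bp from the TSS of xol-1, a switch gene of sex determination and dosage compensation. The peak at X:1344857-1345246 lay 635 bp from the TSS of ins-39, an insulin-like peptide gene, with a signal of 696. Of the X peaks inside genes, the summit at 2997105 was in an intron of Y41G9A.17 (signal 841), that at 6296584 in an intron of mom-1 (809), a gene of Wnt secretion, and that at 5429548 in a coding exon of the polyketide synthase gene pks-1 (773).

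The highest autosomal peaks lay at promoters of translation genes. A peak at III:3867342-3867768 with a signal of 769 had its summit 300 bp from the TSS of rpl-3, a protein of the large ribosomal subunit. The peak at I:9979716-9980090 had a signal of 690 and lay 243 bp from the TSS of eif-3.C, a translation initiation factor subunit. The peak at IV:4749907-4750245 had a signal of 687 and lay 164 bp from the TSS of Y17G9B.5 and 298 bp from that of the ribosomal protein gene rpl-20. The last of the 20 highest nuclear peaks, at V:8500390-8500697 with a signal of 555, lay in an intron of the peroxidasin gene pxn-1, within 200 bp of the snoRNA gene ZK994.7. Each of these 20 nuclear peaks was found within 100 bp among the 862 highest calls of replicate 1 and among those of replicate 2. In the pooled list the 17 highest peaks of all were mitochondrial, with signals from 1505 to 11176. The highest nuclear peak ranked 18 overall. The nuclear ranking was chosen after these values were seen.

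The replicates shared most of their strongest calls. Of the 862 highest calls in replicate 1, 523 (60.7%) had a summit within 100 bp of a summit among the 862 highest of replicate 2. Random shifts gave 1.12% on average and at most 2.44% (permutation p = 0.000999, one-sided, the smallest that 1000 shifts can give). Among the IDR peaks, 830 had a summit within 100 bp in the list of replicate 1, 839 in that of replicate 2 and 808 in both. Across those 808 peaks the replicate signals correlated with Pearson's r = 0.855 on log10 values and Spearman's rho = 0.612 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). Peaks are not independent replicates, so these values describe the repeat of the peak order and not a sampling error. The IDR peaks were also selected from these same lists by IDR analysis. Their presence in both lists and their correlation are therefore not an independent measure of agreement. Without the mitochondrial peaks, Pearson's r was 0.749 and Spearman's rho 0.582 over 788 peaks.

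**Figure D1:**
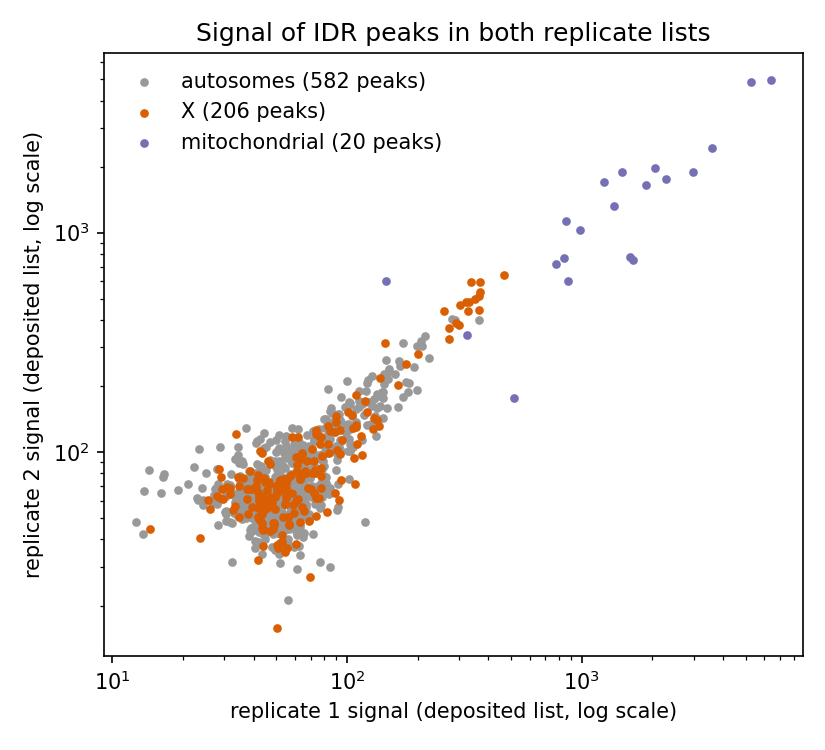
Signal of each IDR peak in the list of replicate 1 (x axis, log scale) against the list of replicate 2 (y axis, log scale), in the units of the deposited lists, for the 808 peaks with a summit within 100 bp in both. Points are single peaks coloured by chromosome class, and most mitochondrial peaks and a group of X peaks stand at the upper right, above nearly all autosomal peaks.

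The X chromosome held more IDR peaks than the weaker calls predicted. Of 839 nuclear IDR peaks, 215 were on X (25.6%, 95% confidence interval 22.8 to 28.7), against 17.4% of 28818 background calls and 17.7% of the nuclear genome length. The odds ratio was 1.63 (Fisher's exact test, adjusted p = 3.67e-08). Chromosome I held 14.8% of the peaks and 17.7% of the background calls (adjusted Fisher p = 0.0829), and chromosome V 12.9% and 15.5% (adjusted p = 0.0829). The shares on II, III and IV were 14.9%, 16.9% and 14.9%, with adjusted p-values of 0.881, 1 and 0.185. Against shares of genome length, V was lower (12.9% against 20.9%, exact binomial test, adjusted p = 1.38e-08) and III higher (16.9% against 13.7%, adjusted p = 0.0181). With the calls of replicate 1 alone, V (adjusted Fisher p = 0.00419) and IV (adjusted p = 0.0491) were lower than the background, and IV was lower in the 431 highest peaks (adjusted p = 0.0286). Because the shares add up to the whole, an X excess by itself lowers those of other chromosomes. In simulated draws with only X raised, to a weight of 1.6, 0.52 other chromosomes were called per draw, against 0.02 with equal weights. The low shares of IV and V are therefore not independent of the X excess.

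Genes for tRNAs were part of this X share. X carries 276 of the 612 nuclear tRNA genes in the annotation (45.1%), and 70 of the 117 nuclear IDR peaks within 200 bp of a tRNA gene were on X. When calls near tRNA genes were left out, a setting chosen after seeing the data, X held 145 of 722 peaks (20.1%) and 17.2% of the background, and the difference no longer passed the threshold (adjusted Fisher p = 0.275, unadjusted p = 0.0459). Among the 201 peaks away from both TSSs and small RNA genes (tRNA, snoRNA and snRNA), 76 were on X, with an odds ratio of 2.46 against the background (95% confidence interval 1.84 to 3.28).

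**Figure D2:**
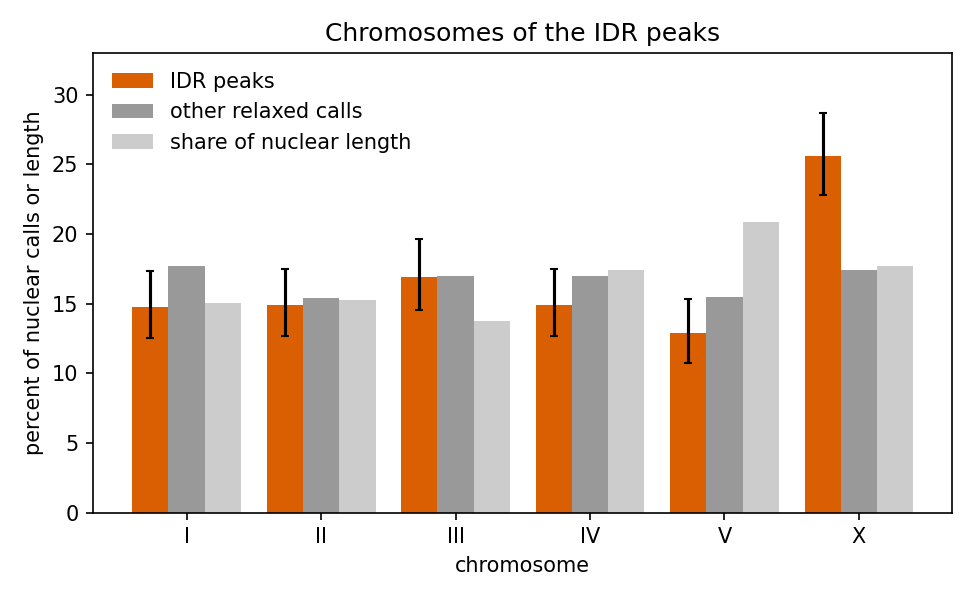
Percent of the 839 nuclear IDR peaks on each chromosome, with 95% Wilson intervals, beside the percent of the 28818 other relaxed calls and the share of nuclear genome length. The bar for X stands at 25.6% against 17.4% and 17.7%, and its interval lies above both.

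Most peaks lay near the start of a protein-coding gene, and this held on the autosomes. In the whole set 536 of 862 summits were within 1000 bp of a TSS (62.2%, 95% confidence interval 58.9 to 65.4). The share of the background calls was 46.6% (odds ratio 1.89, Fisher's exact test, p = 1.23e-19). For the 839 nuclear peaks alone it was 61.1% against the same background (odds ratio 1.81, Fisher p = 7.81e-17). On the autosomes the share was 68.3% of 624 peaks against 48.3% of the background (odds ratio 2.31, Fisher p = 2.77e-23). On X it was 40.5% of 215 peaks against 38.5% (odds ratio 1.09, Fisher p = 0.567). In a test that was not planned, the X and autosomal shares of IDR peaks differed (odds ratio 0.316, Fisher's exact test, p = 1.01e-12). Position was taken from protein-coding gene models only, so a summit called intergenic can lie in a non-coding RNA gene. By these models 556 of the 839 nuclear summits were intergenic (66.3%, against 31.1% of the background, adjusted Fisher p = 6.64e-93). Intronic summits numbered 196 (23.4% against 33.7%, adjusted Fisher p = 2.87e-10). Coding exons held 45 summits (5.36% against 28.2%, adjusted Fisher p = 1.58e-62), 3′ UTRs 14 (1.67% against 5.02%, adjusted p = 1.35e-06) and 5′ UTRs 26 (3.10% against 1.77%, adjusted p = 0.00965).

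Small RNA genes were among the most enriched features. A tRNA gene lay within 200 bp of 125 summits (14.5%, 95% confidence interval 12.3 to 17), against 1.15% of the background (odds ratio 14.6, Fisher's exact test, adjusted p = 1.42e-84). Genes for snoRNAs, which guide modification of other RNAs, were at 71 summits (8.24% against 0.330%, odds ratio 27.1, adjusted Fisher p = 1.02e-63). Genes for snRNAs, a class that in this annotation includes spliceosomal and spliced-leader RNAs, were at 32 summits (3.71% against 0.149%, odds ratio 25.8, adjusted Fisher p = 4.01e-29). The broad class annotated only as ncRNA, with 7764 genes, was at 222 summits (25.8% against 5.16%, odds ratio 6.38, adjusted Fisher p = 6.17e-84). Each class was counted on its own, so summits also near a small RNA gene were not removed from this class. In contrast, piRNA genes were at 6 summits (0.696% against 2.29%, odds ratio 0.299, adjusted Fisher p = 9.35e-04). The shares near miRNA genes (3 summits, adjusted Fisher p = 0.486) and antisense RNA genes (4 summits, adjusted p = 0.109) were not past the threshold. Within 1000 bp miRNA genes passed it (15 summits, odds ratio 2.26, adjusted Fisher p = 0.00799), and with the calls of replicate 2 alone antisense RNA genes did (5 summits, adjusted p = 0.0285).

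The 5 summits at rRNA genes were all mitochondrial. Within 200 bp of an annotated rRNA gene there were 0 of 839 nuclear summits and 0 of 28818 background calls, so nuclear rRNA genes could not be compared. The nuclear shares were 117 peaks for tRNA, 71 for snoRNA and 32 for snRNA genes. The share at lincRNA genes (7 summits, adjusted Fisher p = 0.0450) was lost at a distance of 1000 bp (adjusted p = 0.241) and in the 431 highest peaks (adjusted p = 0.0850), and that at piRNA genes at 1000 bp (adjusted p = 0.0587). Many tRNA genes have near-identical copies. Of the 117 nuclear peaks near a tRNA gene, 76 (65.0%) held a sequence of 31 bp within 50 bp of the summit that occurs elsewhere in the genome, as did 13 of 32 near an snRNA gene and 6 of 71 near a snoRNA gene. Which copy was occupied is therefore uncertain for those peaks.

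Several RNA genes at strong peaks were chosen after their values were seen. The genes sls-2.4 (I:4172206-4172315), sls-2.1 (II:5844865-5844974) and sls-2.2 (II:5543598-5543707), which encode the spliced-leader RNA SL2, were at peaks with signals of 519, 500 and 401. In total 8 of the 18 annotated sls-2 genes had an IDR summit within 200 bp, and 0 of the 12 annotated sls-1 genes. Background calls at sls-1 genes were not counted, so this 0 does not show a difference in occupancy between the families. Of the snoRNA genes, C51F7.4 and C51F7.3 shared a peak on V with its summit at 12303660 and a signal of 439.

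**Figure D3:**
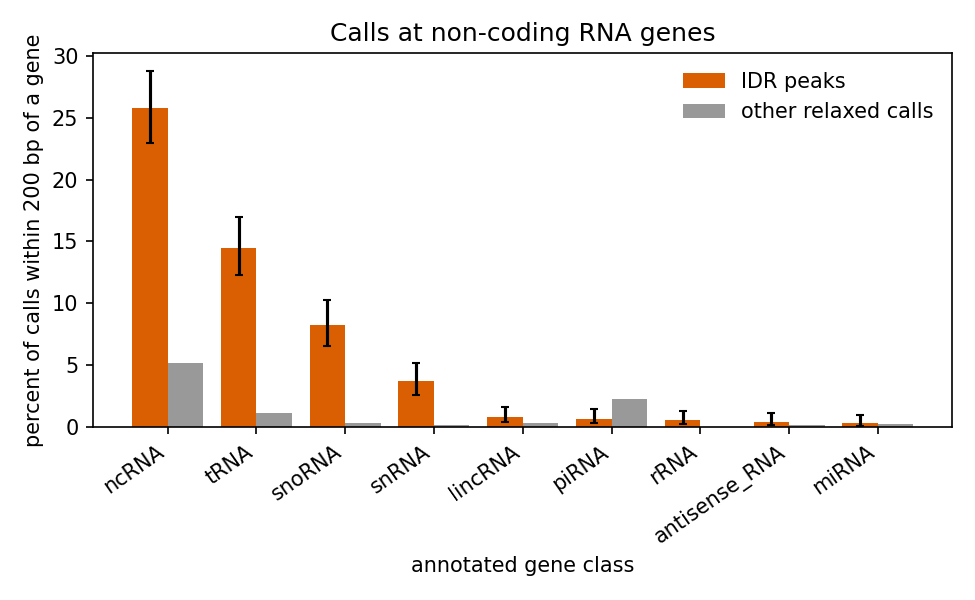
Percent of the 862 IDR summits, with 95% Wilson intervals, and of the 28818 other relaxed calls that lie within 200 bp of a gene of each non-coding class (x axis). The IDR bars for tRNA (14.5%), snoRNA (8.24%) and snRNA (3.71%) stand above those of the other calls, and the bar for piRNA (0.696%) stands below.

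Among the gene lists, those of protein synthesis, protein folding and respiration gave the lowest p-values. In total 673 genes were bound, 7.09% of the 9495 genes with any relaxed call near a TSS. Bound means only that an IDR summit lay nearby. Lists of other tagged proteins were not analysed here, so whether such promoters are recovered with many tagged proteins stays open. Of the cytosolic ribosomal protein genes 23 of 77 (29.9%) were bound, against 6.90% of all other genes (odds ratio 5.75, Fisher's exact test, adjusted p = 5.08e-08). Besides rpl-3 and rpl-20, the highest peaks were at rpl-15 (IV:654790-655065, signal 433) and rpl-35 (III:7854552-7854840, signal 385). Of the translation initiation and elongation factors 9 of 36 were bound (25%, odds ratio 4.42, adjusted Fisher p = 0.00756). They included eif-3.C, eef-2 (I:9163388-9163621, summit in the 5′ UTR, signal 274), eef-1G (V:10965498-10965947, signal 188) and eif-2Bgamma (II:6968133-6968582, signal 170). The eif-2Bgamma summit lay 710 bp from its TSS and within 200 bp of sup-39, annotated as an snRNA gene. Mitochondrial ribosomal protein genes were bound in 5 of 58 cases (adjusted Fisher p = 0.834), among them mrpl-28 (signal 182) and, at a summit also within 200 bp of the snoRNA gene T08B2.13, mrpl-23 (106). Of 21 aminoacyl-tRNA synthetase genes 1, ears-2, was bound (adjusted Fisher p = 1).

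Of the heat shock and chaperone genes 11 of 42 were bound (26.2%, odds ratio 4.71, Fisher's exact test, adjusted p = 0.00188). The highest peaks were at hsp-60, the mitochondrial chaperonin (III:1619009-1619288, signal 416), dnj-9 (II:4851702-4851958, signal 392), hsp-90 (V:14685614-14685907, in an intron, signal 362) and dnj-13 (II:11545361-11545599, signal 272). Of the genes for the respiratory chain and ATP synthase 12 of 61 were bound (19.7%, odds ratio 3.25, adjusted Fisher p = 0.00810). These included the cytochrome c oxidase subunit genes cox-5A (III:12905065-12905353, signal 489) and cox-6A (III:5080688-5081137, signal 215), the ATP synthase gene atp-1 (I:12652159-12652359, signal 234) and the complex I gene nduf-2.2 (III:6464204-6464653, signal 164). The cox-6A summit lay 811 bp from its TSS and within 200 bp of the snRNA gene F54D8.7. The IDR summits included 190 near the TSSs of more than 1 gene. When each summit was given to its nearest TSS only, the heat shock list fell to 5 bound members and below the threshold (adjusted Fisher p = 0.268). The respiratory list was lost at 500 bp (adjusted Fisher p = 0.0896) and in the 431 highest peaks (adjusted p = 0.0579).

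Heterochronic and cell cycle genes were also bound more often than other genes. Of the heterochronic genes, which time larval development, 4 of 11 were bound (36.4%, odds ratio 7.53, Fisher's exact test, adjusted p = 0.0294). They were nhl-2 (III:4899818-4900042, signal 268) and ain-1 (X:16612252-16612701, signal 215), both cofactors of microRNA silencing, lin-66 (IV:13887412-13887861, signal 139) and the Period homologue lin-42 (II:1239460-1239909, signal 87.2). The ain-1 peak had no summit within 100 bp in the list of replicate 2, nor the lin-42 peak in that of replicate 1. The list was below the threshold at 500 bp (adjusted Fisher p = 0.462), with the nearest TSS only (adjusted p = 0.0964) and in the 431 highest peaks (adjusted p = 0.0536). Of the cell cycle and DNA replication genes 10 of 61 were bound (16.4%, odds ratio 2.59, adjusted Fisher p = 0.0458), led by cdc-48.1 (II:10563436-10563698, signal 372), the PCNA gene pcn-1 (IV:4049610-4049816, signal 253), the licensing factor gene cdc-6 (signal 157) and rfc-4 (144). This call was lost with the calls of replicate 2 alone (adjusted Fisher p = 0.290) and of replicate 1 alone (adjusted p = 0.233). It was also lost at 500 bp (adjusted Fisher p = 0.349), at 2000 bp (adjusted p = 0.0515), with the nearest TSS only (adjusted p = 0.0964) and in the 431 highest peaks (adjusted p = 0.161).

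Chemoreceptor genes, which act in small sets of sensory neurons, were bound less often than other genes. Of 212 with a relaxed call 5 were bound (2.36% against 7.20%, odds ratio 0.312, Fisher's exact test, adjusted p = 0.0258), the strongest at sre-23 (signal 235.2), srh-16 (188), sri-5 (174) and srz-97 (108). The call was lost at 500 bp (adjusted Fisher p = 0.462), with the nearest TSS only (adjusted p = 0.268) and in the 431 highest peaks (adjusted p = 0.2004). The summits at sre-23 and srz-97 also lay within 200 bp of the snoRNA gene ZK265.10 and the snRNA gene F08H9.11. Without calls near small RNA genes, a setting chosen after seeing the data, 2 of 206 chemoreceptor genes were bound (0.971%, adjusted Fisher p = 0.00557). Histone genes were bound in 8 of 45 cases (adjusted Fisher p = 0.0508), with his-67 and his-68 sharing a peak at I:9988835-9989156 (signal 524). Of the 5 nuclear IDR peaks near the TSS of a histone gene 1 held a repeated sequence of 31 bp, and the his-67 and his-68 peak did not. Cuticle collagen genes were bound in 2 of 115 cases, col-63 and col-185 (adjusted Fisher p = 0.0599). None of 23 pan-neuronal genes with a relaxed call (adjusted Fisher p = 0.681), of 32 intestinal genes (adjusted p = 0.387) or of 16 vacuolar ATPase genes (adjusted p = 0.834) was bound. Muscle genes were bound in 2 of 34 cases, unc-112 and act-4 (adjusted Fisher p = 1), and germline genes in 3 of 45, including syp-4 and him-5 (adjusted p = 1). The summits at col-185, syp-4 and him-5 were also within 200 bp of a tRNA, an snRNA and a snoRNA gene, respectively. Of the transcription factor lists, homeobox genes had 1 bound of 53, ceh-38 (adjusted Fisher p = 0.387), and nuclear hormone receptors 4 of 105, including nhr-47 and nhr-1 (adjusted p = 0.499). The other 14 lists had adjusted Fisher p-values from 0.0920, for lysosomal and autophagy genes (8 of 52 bound, including vps-4 and epg-8), to 1.

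**Figure D4:**
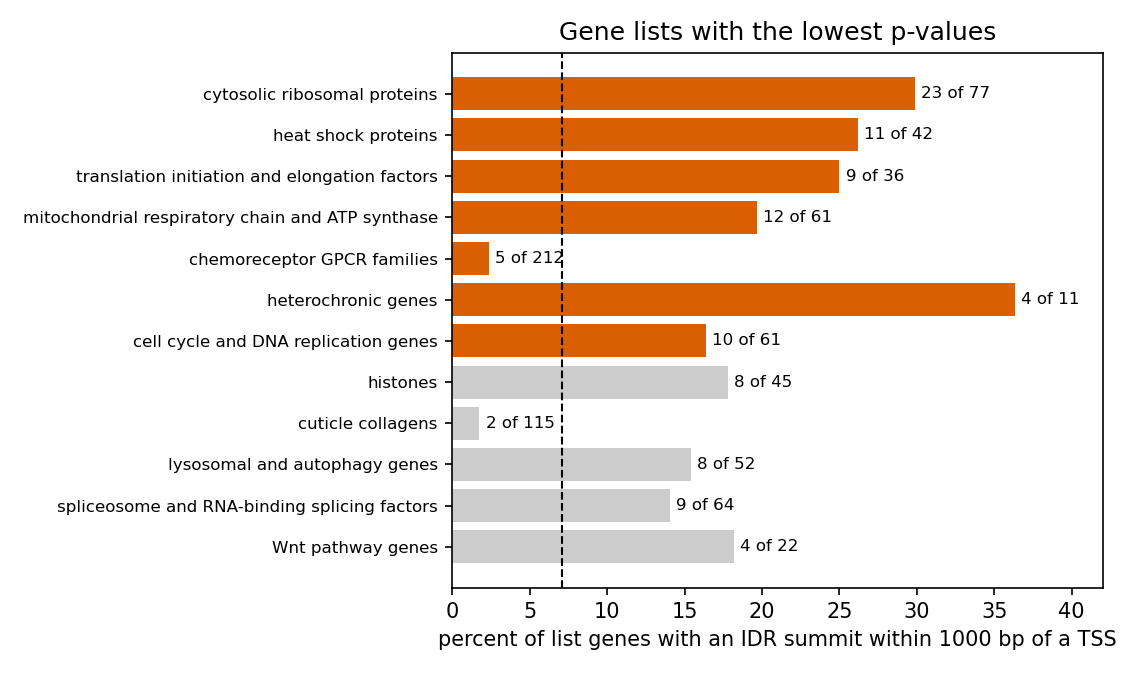
Percent of the genes of each list, among those with any relaxed call, that had an IDR summit within 1000 bp of a TSS (x axis), for the 12 lists with the lowest p-values (y axis). Orange bars have an adjusted p below 0.05, grey bars do not, labels give bound and tested genes, and the dashed line marks the 7.09% of all 9495 genes that were bound, with chemoreceptors and collagens below it.

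The sequence at the summits was richer in G and C than its surroundings. Within 50 bp of nuclear summits the GC content averaged 47.8% ± 9.09 (SD over 839 peaks), against 36.9% in the flanks. At background calls it was 38.1% and 36.7%. Of the 2080 canonical 6-mers, 375 were more frequent at the summit and 233 less frequent. The 5 with the lowest adjusted p were AAAATT (21.8% of summits against 42.3% of flanks, adjusted exact p = 2.37e-17), AAAAAA (19% against 38.4%, adjusted p = 3.38e-16), AAAAAT (25.2% against 45.7%, adjusted p = 3.38e-16), TTAAAA (11.6% against 28.3%, adjusted p = 3.48e-15) and GAGAGA (22.5% against 8.70%, adjusted p = 3.48e-15). Against the same summit sequences shuffled with their dinucleotides kept, a setting chosen after seeing the data, 99 were more frequent and 76 less frequent. There GAGAGA had the lowest p-value (22.5% against 9.98%, adjusted exact p = 1.41e-13).

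Of the 30 fixed motifs, 8 were more frequent at the summit than in the flanks (exact McNemar test). They were the GAGA repeat (22.5% against 8.70%, adjusted exact p = 2.51e-16), the E2F site (10.4% against 2.90%, adjusted p = 2.28e-09), the CTCTC element (9.98% against 3.60%, adjusted p = 1.78e-07) and the B box of RNA polymerase III genes (3.94% against 0.464%, adjusted p = 2.97e-07). The others were the GC box (7.42% against 2.44%, adjusted exact p = 4.76e-06), the CA repeat (14.4% against 7.66%, adjusted p = 2.64e-05), the RUNX site (9.74% against 6.5%, adjusted p = 0.0251) and the E-box CACGTG (3.13% against 1.51%, adjusted p = 0.0474). The CTCTC element contains the GAGA repeat on the opposite strand, so these 2 motifs overlap. Another 11 were less frequent. Among these the SL1 acceptor-like sequence was at 6.73% of summits and 19.4% of flanks (adjusted exact p = 2.97e-13), the T block at 8.005% and 19.8% (adjusted p = 1.49e-12), the Inr-like sequence at 80.05% and 92.0% (adjusted p = 3.26e-12) and the HOX/PBC site at 3.71% and 8.58% (adjusted p = 7.92e-05). The GATA site was at 14.3% and 21.6% (adjusted exact p = 3.36e-04), the CCAAT box at 16.5% and 23.5% (adjusted p = 7.80e-04) and the TATA box at 7.31% and 12.4% (adjusted p = 0.00113). The TCF site was at 2.32% and 5.45% (adjusted exact p = 0.00234), the heat shock element at 3.83% and 7.19% (adjusted p = 0.00692), the forkhead site at 7.89% and 11.3% (adjusted p = 0.0304) and the TAATTA homeodomain site at 3.02% and 5.10% (adjusted p = 0.0474).

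Against the shuffled summit sequences 6 motifs passed the threshold. Of the 8, the GAGA repeat (adjusted exact p = 2.04e-15), CTCTC element (adjusted p = 2.92e-08), B box (adjusted p = 1.94e-07), CA repeat (adjusted p = 2.42e-07) and GC box (adjusted p = 9.34e-04) remained more frequent, and the E2F site (adjusted p = 0.303), RUNX site (adjusted p = 0.546) and E-box (adjusted p = 0.977) did not pass. None of the 11 lower calls passed, among them those of the GATA site (14.3% against 14.7%, adjusted exact p = 0.977), the T block (8.005% against 8.82%, adjusted p = 0.838), the CCAAT box (16.5% against 16.9%, adjusted p = 0.977), the TCF site (adjusted p = 0.332) and the HOX/PBC site (adjusted p = 0.546). The other motif past the threshold was the ETS core, which was not past it against the flanks and was less frequent at the summit (1.51% against 5.10%, adjusted exact p = 1.35e-04). Against the flanks, the lower calls of the heat shock element (adjusted exact p = 0.686), the CCAAT box (adjusted p = 0.0592) and the HOX/PBC site (adjusted p = 0.0974) and the higher call of the E-box (adjusted p = 0.439) were lost with the calls of replicate 1 alone, and that of TAATTA with those of replicate 2 alone (adjusted p = 0.0929). The higher call of the RUNX site was lost in windows of 25 bp (adjusted exact p = 0.477) and 100 bp (adjusted exact p = 0.0788). The lower call of TAATTA was also lost in both windows (adjusted exact p = 0.0884 and 0.0871) and without mitochondrial peaks (adjusted p = 0.0576), and that of the heat shock element in the 25 bp window (adjusted p = 0.266). Against relaxed calls near a TSS, the calls of the E-box (adjusted Fisher p = 0.493), heat shock element (adjusted p = 0.0560), CCAAT box (adjusted p = 0.0875) and TCF site (adjusted p = 0.0509) were lost. The ETS core was lower there too (1.12% against 3.85%, adjusted Fisher p = 6.55e-04). The E-box CAGCTG gained a higher call with replicate 2 alone (adjusted exact p = 0.0196) and in the 100 bp window (adjusted exact p = 0.0313). In that window the SMAD site did as well (adjusted exact p = 0.00719).

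Neither the gene of the tagged protein nor unc-119, the gene mutated in the strain, was bound. Within 20 kb of F10B5.3 (II:8147184-8150030) the highest pooled relaxed signal was 90.2, at percentile 75.96 among windows around protein-coding genes, and the window held 13 calls. In the replicate lists the percentile was 70.8 for replicate 1 and 83.3 for replicate 2. By number of calls the window was at percentile 58.2 in the pool. With 16 calls it was at percentile 90.4 in replicate 1, and with 20 calls at 91.4 in replicate 2. Within 5 kb of the gene there was no relaxed call. The lowest signal of an IDR peak was 86.5, so the highest call within 20 kb of F10B5.3 was itself an IDR peak. Within 20 kb of unc-119 (III:10902641-10908935) the highest signal was 42.2, at percentile 28.0, and within 5 kb the percentile was 65.3.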

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

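The test in this part was chosen only after the result was seen. The mitochondrial chromosome, which the comparison of chromosomes did not use, held 23 IDR peaks. They include the 17 highest signals of the set. The pooled calls covered 87.4% of the 13794 bp of this chromosome, a spread that background reads from DNA present in many copies per cell would give. High-copy DNA is therefore a candidate explanation. The share is the length of called intervals and not read coverage, and intervals of up to 3803 bp held several summits. It cannot tell such a background from strong sites that the caller merged. Since the calls were made against a control alignment that was not analysed here, it stays open whether the control held the same excess. The single group of samples gave no biological explanation to test.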

How the results depend on the processing

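Of 59 alternative values for the main results, 49 kept their direction and their side of the threshold or stayed within 1.5 times the main count. The peak count was 431 among the highest peaks by construction. The X share was 20.1% when calls near tRNA genes were left out of the peaks and the background. The 7 gene lists past the threshold became 4 at 500 bp, 3 with the nearest TSS only, 4 in the 431 highest peaks and 11 with all protein-coding genes as background. Of these, 3, 3, 3 and 7 were among the 7 main lists. The cause was not tested. Without calls near small RNA genes all 7 were kept among 10, and with nuclear or with autosomal calls only among 8. At 2000 bp and with each replicate alone 8 lists passed, of which 6 were among the 7. The 19 fixed motifs became 6 against shuffled sequences, of which 5 were among the 19, and the 608 6-mers became 370 in the 25 bp window and 175 against shuffled sequences, which differ from the flanks in holding the summit's own base composition. Under shuffling the forkhead site (7.89%), TAATTA (3.02%), the heat shock element (3.83%), the SL1 acceptor-like sequence (6.73%), the TATA box (7.31%) and the Inr-like sequence (80.05%) turned from lower to higher at the summit without passing the threshold. The percentile of the F10B5.3 locus fell to 11.2 within 5 kb, where no call lay. Of 291 alternative values for single classes, lists, motifs, peaks and the unc-119 locus, 239 kept their call, 42 lost it, 2 gained it, 2 moved and 6 reversed. The 2 gains were those of miRNA genes within 1000 bp and of antisense RNA genes with replicate 2 alone. Only the 7 main gene lists were followed here, so lists that newly passed in a setting are not counted as gains. The new motif calls given above are not counted either. No paired analysis was possible because there is only 1 group. Depth was unknown, so the number of weak sites missed cannot be stated.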

Other observations

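The tests of the sequence word and of the X share of background calls, the removal of calls near tRNA genes and the placement of peaks were chosen only after the peak positions were seen. Each nuclear peak was placed by what its summit lay at. A tRNA, snoRNA or snRNA gene was within 200 bp of 220 of 839 peaks (26.2%), and 418 more (49.8%) were within 1000 bp of a TSS. The remaining 201 (24.0%) were at neither. On X 76 of 215 peaks (35.3%) were at neither, with a median signal of 133, and on the autosomes 125 of 624 (20.03%), with a median signal of 103 (odds ratio 2.18, Fisher's exact test, p = 1.16e-05). The highest autosomal peak of this kind had a signal of 350, against 1110 on X. The GAGAGA word was within 50 bp of 16.8% of the summits at small RNA genes, 23.7% of those at TSSs only and 28.9% of those at neither. On the autosomes these shares were 12.8%, 22.5% and 31.2%, and on X 25%, 29.9% and 25%. Whether X and the autosomes differ in this was not tested.

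The X excess was tested against technical explanations. A surplus of reads along all of X would raise weak calls there too, but 17.4% of the background calls were on X, against 17.7% of genome length. GC content does not account for it, since the odds ratio over strata of summit GC was 1.66 (95% confidence interval 1.42 to 1.95). Without calls that hold a repeated 31-mer it was 1.41 (1.18 to 1.68). The tRNA genes on X account for part of it. Without calls near them the odds ratio was 1.21 (1.01 to 1.46, not adjusted), and the adjusted Fisher p was 0.275. The odds ratio of 1.21 alone does not settle whether the tRNA genes are the whole cause. The 201 peaks away from TSSs and small RNA genes held no call near a tRNA gene by definition. Their odds ratio for X was 2.46 (1.84 to 3.28). For peaks of this kind this value argues against the tRNA genes as the whole cause.

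A hypothesis for the strongest X peaks is that they lie at recruitment sites of the dosage compensation complex, which lowers expression of both X chromosomes in hermaphrodites and loads at X elements with a G-rich word. The core GCGCAGGGAG, with at most 1 mismatch, was within 50 bp of 18 of 76 X summits away from TSSs and small RNA genes (23.7%, 95% confidence interval 15.5 to 34.4) and of 0 of 125 such autosomal summits (Fisher's exact test, p = 6.13e-09). Of all 215 X peaks 19 held it (8.84%), and of all 624 autosomal peaks 3 (0.481%). Of the 3001 background X calls of the same kind 12 held it (0.3999%). It was at 10 of the 16 X peaks among the 20 highest nuclear peaks, and at 0 of 70 X peaks near tRNA genes. Without a mismatch the word was at 4 of the 76 X summits (5.26%) and at 2 of the 16 highest X peaks, so most of these matches have 1 mismatch. The word may therefore mark a share of the X peaks. Whether the tagged protein acts there, or whether these sites are recovered with many tagged proteins, stays open, because lists of other proteins were not analysed here.

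The excess at small RNA genes was tested against repeats and base composition. Without calls that hold a repeated 31-mer, the odds ratio for a tRNA, snoRNA or snRNA gene was 20.9 (95% confidence interval 16.7 to 26.3), and over strata of summit GC it was 14.7 (12.2 to 17.8), against 21.5 for all nuclear calls. Repeated sequence and GC content, each taken alone, thus leave most of the excess. They were not tested together. The repeat filter kept 125 of the 220 peaks at small RNA genes, and its odds ratio describes only the calls that were kept. That heavily transcribed loci are pulled down whatever the tagged protein stays open and was not tested, and no biological explanation was tested.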
